A study of Mus musculus with 11 samples.

How the data were processed

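RNA levels were measured in mouse fetal gonads on 11 Illumina BeadChip arrays of 45281 probes each. Per the labels, germ cells were purified by fluorescence-activated cell sorting on green fluorescent protein under Pou5f1 regulation, from gonads at embryonic days 11.5 (labelled male/female), 13.5 (males) and 15.5 (males), with 3 biological replicates each. The GFP-negative, non-germ fraction of male gonads at day 13.5 was a control with 2 replicates. The labels do not say how many embryos went into a replicate. RNA was isolated with an on-column DNase step, amplified and biotin-labelled, and every sample had the same protocol in the labels.

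The deposited table of non-normalized values holds, per the file headers, the signal intensity of each probe on each array on a linear scale, neither background-subtracted nor scaled between arrays. Beside each intensity column the deposited table gives a detection p-value. A second table by the authors holds intensity values that are a straight line of each array's own signals, with the first array unchanged, on a linear scale and not centred. The method and software behind that rescaling are not stated. The direction of no value was in doubt, since none is a ratio. Its column medians were 315.07, 326.05 and 325.53 at E11.5, 325.85, 331.48 and 328.61 at E13.5, 341.75, 316.98 and 328.12 at E15.5, and 321.86 and 318.75 in the non-germ cells. The median signals of the non-normalized table ran from 230.06 to 315.07. The number of arrays limits the precision of every value.

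Values were analysed in R 4.3.3 with limma 3.58.1. The function neqc corrected the background from the detection p-values, added an offset of 16, scaled the 11 arrays by quantiles and took log2. A probe was kept when its detection p-value was below 0.01 on at least 2 of the 11 arrays, which held for 21943 probes. The probe table gave 1 gene symbol to 34885 probes, several to 18 and no entry to 10378. Of named probes, 99.7% matched the reference annotation by Entrez number. The 3792 kept probes with no or several symbols were left out, and each gene was represented by the kept probe with the highest mean over all arrays, giving 11598 genes. For 4439 of these more than 1 probe was kept.

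One linear model with a mean for each of the 4 groups was fitted to all 11 arrays with 7 residual degrees of freedom, and limma's empirical Bayes step added 3.54 prior degrees of freedom. The contrasts were E13.5 against E11.5, E15.5 against E13.5 and E15.5 against E11.5 germ cells, germ against non-germ cells at E13.5, and the second interval minus the first. Any change over the 3 stages was tested with the moderated F statistic. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and a second count asked for at least a 2-fold change in addition. Fold changes are differences of group means on the log2 scale, given with the standard error of the fit. Where no array of a group detected a gene, the fold is a lower bound computed against the lowest normalized value that counted as detected on each array of that group. Genes called and at least 4-fold higher in germ than in non-germ cells at E13.5, or the reverse, were taken as enriched and followed from E11.5 to E15.5. The E11.5 and E15.5 arrays entered this choice of genes through normalization, the detection filter, the choice of probe and the pooled spread, but not through the difference itself.

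Gene lists of pathways, cell type markers, Y-linked genes and stress genes were written before the data were examined, as were the samples, the contrasts, the rule for named genes and the alternatives. The 29 lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data and with fry. Camera compares the members with all other genes, whereas fry asks whether the members move at all, and adjusted p-values run over the lists within a contrast. Xist, on a list of its own, was not set-tested. Other lists hold 11 of 15 male germ cell differentiation genes, 5 of 22 genome defence genes, 5 of 13 Nodal genes, 3 of 14 each of cell cycle inhibitors and adhesion genes, and 3 of 16 immediate early genes. They hold 2 each of pluripotency (20), early primordial germ cell (16), FGF (13) and DNA methylation genes (13), 1 each of imprinted (26), Sertoli (19), endothelial (13) and ovarian genes (4), and 0 of the rest.

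Named genes follow a fixed rule. For each contrast of groups it takes the 6 largest rises and 6 largest falls past the threshold with no overlap between the groups and detection in both, and the 4 largest lower bounds in each direction among genes detected on all arrays of one group and on none of the other. From each list described it takes up to 2 members with the largest rise and 2 with the largest fall past the threshold, or the member with the smallest adjusted p where none passed. Pou5f1, Xist, Ddx3y, Eif2s3y, Nanog, Sox2, Ddx4, Dazl, Nanos2, Dnmt3l, Stra8, Sox9 and Amh were always taken. Predicted genes and those with only a clone or RIKEN name could be passed over.

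The code was tested on simulated data with known changes, in groups of the sizes used here, with 65 to 67 changed genes per fold. It recovered 4.55%, 37.3% and 93.9% of genes changed 1.5, 2 and 4-fold between E11.5 and E13.5. The shares were 4.48%, 30.3% and 93.9% between E13.5 and E15.5, 0%, 31.3% and 95.5% between E11.5 and E15.5, and 0%, 17.9% and 81.8% for germ against non-germ cells. They were 9.09%, 70.8% and 98.5% for the difference between the intervals and 1.49%, 41.5% and 93.9% for any change. Of 14654 to 15146 unchanged genes, 2 to 8 were called. With so few changed genes a share moves by several points with the genes drawn. The simulated fits held 14896 to 15390 genes, few of them changed, whereas 18.8% to 57% of genes were called per contrast in the data. Adjustment over all genes is then stricter in the simulation, and its noise was independent between genes. These shares therefore do not give the recovery in the data.

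Alternatives were no background correction, an offset of 50, the authors' table, median scaling, cyclic loess, normalization or fits of the compared groups alone, other detection filters, the mean of a gene's probes, every probe on its own, a replicate block, an intensity trend with robust variances, array weights, stricter thresholds, other set tests and leaving out each array. Calls and list tests without E15.5 replicate 2 were added after its values were seen. No array was left out of the main results. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.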

Results

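The series followed RNA levels in mouse fetal germ cells, the precursors of eggs and sperm, sorted from gonads by green fluorescent protein (GFP) under Pou5f1 regulation. There were 3 arrays of germ cells from E11.5, labelled male/female, 3 from male gonads at E13.5 and 3 from male gonads at E15.5. The GFP-negative, non-germ fraction of E13.5 male gonads was measured on 2 arrays as a control. Of 45281 probes, 14860 to 18657 were detected per array.

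Pou5f1, the pluripotency gene whose reporter was sorted, was at a normalized log2 intensity of 11.05 ± 0.11 (mean ± SD, n = 3) at E11.5, 10.67 ± 0.12 at E13.5 and 10.42 ± 0.29 at E15.5. In non-germ cells it was undetected, at 4.89 ± 0.26 (n = 2). The pluripotency factor Nanog was at 11.98 ± 0.37, 11.86 ± 0.22 and 10.40 ± 0.34 in the 3 stages against 6.00 ± 0.049 in non-germ cells. Sox2, another such factor, was at 11.77 ± 0.18, 10.95 ± 0.13 and 9.02 ± 0.54 against 5.06 ± 0.039, undetected. The germ cell RNA helicase Ddx4 measured 11.31 ± 0.081, 12.44 ± 0.17 and 12.65 ± 0.13 against 5.35 ± 0.02. The germ cell RNA-binding protein Dazl measured 12.21 ± 0.19, 12.92 ± 0.20 and 12.19 ± 0.27 against 5.59 ± 0.051, undetected. Nanos2, an RNA-binding protein of the male germ line, was undetected at E11.5 (5.15 ± 0.12) and in non-germ cells (4.95 ± 0.054). It stood at 11.38 ± 0.36 and 11.30 ± 0.34 at E13.5 and E15.5. Dnmt3l, a cofactor of de novo DNA methylation, was undetected at E11.5 (4.76 ± 0.16) and in non-germ cells (4.72 ± 0.06). It was detected on 1 of 3 arrays at E13.5 (6.08 ± 0.99) and at 11.95 ± 0.25 at E15.5. Stra8, a gene of meiotic entry, was undetected at E11.5 (4.49 ± 0.033), at E13.5 (4.70 ± 0.14) and in non-germ cells (4.46 ± 0.051). It was detected on 2 of 3 arrays at E15.5 (6.61 ± 1.27). The Sertoli cell factor Sox9 was at 6.22 ± 0.68, 6.64 ± 1.68 and 10.79 ± 1.08 in germ cells against 11.73 ± 0.71 in non-germ cells. The Sertoli cell hormone Amh was undetected in germ cells (4.85 ± 0.075, 5.23 ± 0.34 and 5.55 ± 0.20) and detected on both non-germ arrays (5.88 ± 0.00031). Xist, the RNA of the inactive X chromosome, was at 7.06 ± 0.47, 6.14 ± 0.47 and 5.91 ± 0.13 in germ cells and undetected in non-germ cells (4.85 ± 0.18). The Y-linked Eif2s3y was at 10.20 ± 0.68, 11.24 ± 0.29 and 11 ± 0.25 against 10.54 ± 0.20. Y-linked Ddx3y had no named probe. The plot of 12 genes on each array shows several of these courses.

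**Figure D1:**
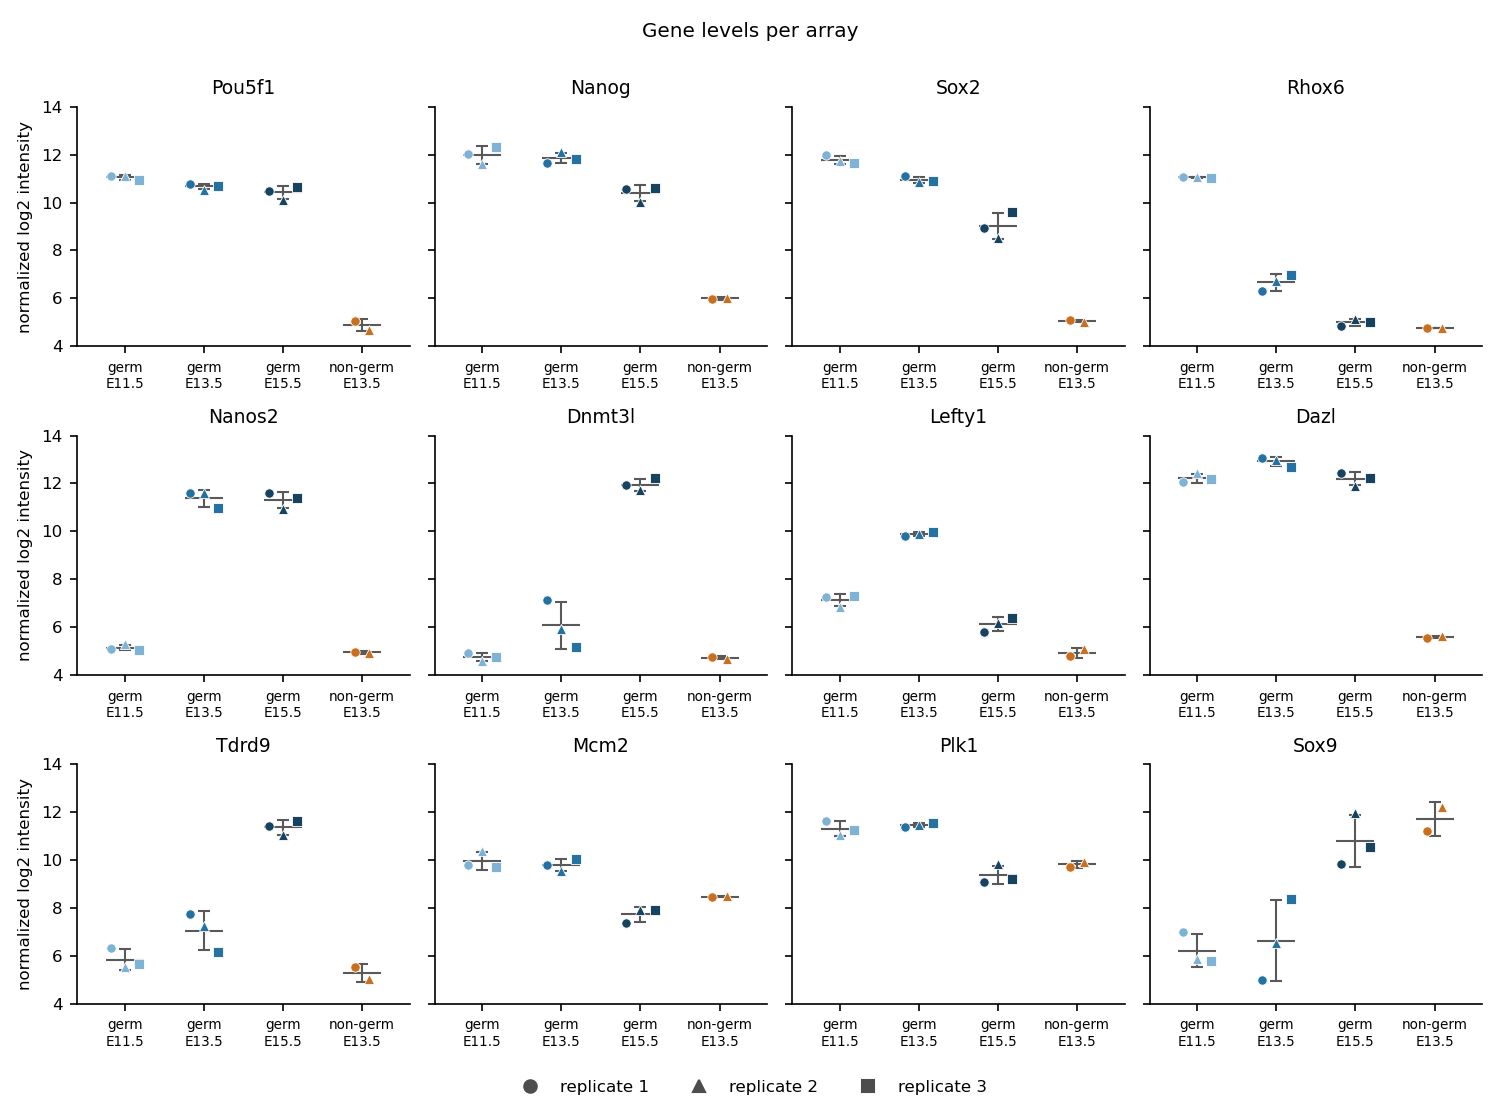
Normalized log2 intensity of 12 genes on each of the 11 arrays, by group, with marker shape by replicate number and the group mean ± SD beside the points. Nanos2 stands near 11.4 at E13.5 against 5.15 at E11.5, and Dnmt3l near 12.0 at E15.5 against 6.08 at E13.5.

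Germ cell arrays resembled each other within a stage, except that 1 E15.5 array stood apart and was higher in transcripts of other gonadal cells. Pearson r across genes, which are not independent replicates, was 0.978 to 0.981 within E11.5, 0.978 to 0.986 within E13.5, 0.912 to 0.972 within E15.5 and 0.984 between the non-germ arrays. With E15.5 replicates 1 and 3, E15.5 replicate 2 correlated at r = 0.912 and 0.926, whereas E11.5 arrays correlated with E13.5 germ cell arrays at 0.923 to 0.945. E15.5 replicate 2 correlated with the non-germ arrays at r = 0.849, against 0.687 and 0.696 for E15.5 replicates 1 and 3. Its mean log2 intensity over 17 markers of gonadal interstitial cells was 9.30, against 6.39 and 6.28 in E15.5 replicates 1 and 3 and 10.2 and 10.4 in the non-germ arrays. Over 19 Sertoli cell markers it was 8.26 against 6.20 and 6.83, over 9 fetal Leydig cell markers 8.13 against 5.97 and 5.76, and over 7 erythroid markers 8.00 against 5.54 and 5.98. Non-germ replicates 1 and 2, close in interstitial markers, differed in erythroid (11.2 and 8.66), endothelial (6.68 and 7.72) and fetal Leydig means (6.68 and 7.62). The first principal component held 51.9% of the variance and the second 29.1%. Because of this array, comparisons with E15.5 are also given without its replicate 2, a choice made after its values were seen.

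**Figure D2:**
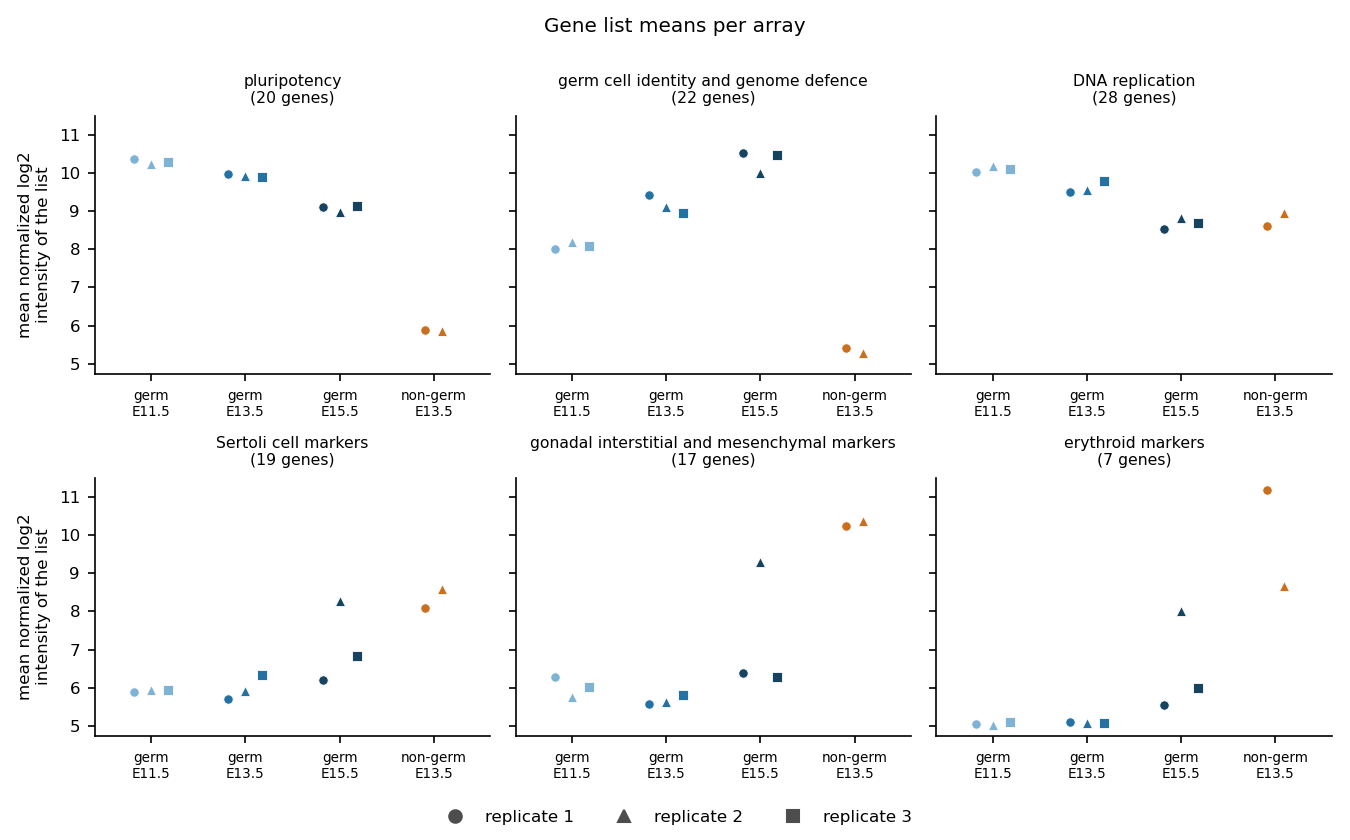
Mean normalized log2 intensity of the measured genes of 6 lists on each of the 11 arrays, with markers by replicate number and no error bars. In E15.5 replicate 2 the Sertoli (8.26), interstitial (9.30) and erythroid (8.00) means lie above those of both other E15.5 arrays.

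The control comparison asked which genes mark the GFP-positive against the GFP-negative fraction of E13.5 male gonads. Germ cells held the pluripotency gene Sall4 at log2 8.46 ± 0.24 above non-germ cells (difference ± SE, 3 against 2 arrays; adjusted p = 4.32e-09). The germ cell helicase Ddx4 was higher by 7.09 ± 0.16, the PIWI protein Piwil2 by 6.03 ± 0.24, the nuclear receptor Esrrb by 5.96 ± 0.21, Nanog by 5.86 ± 0.26 and the RNA-binding Lin28a by 5.78 ± 0.23. Genes undetected in non-germ cells included Dppa5a, at least 182-fold higher in germ cells, Dazl at least 137-fold, Dppa3 at least 119-fold and Trim71 at least 75.6-fold. Pou5f1 was at least 28.9-fold higher and Sox2 at least 35-fold (adjusted p from 3.65e-09 to 1.26e-07). Non-germ cells were higher in the collagen Col3a1 (-7.61 ± 1.54, adjusted p = 0.00164), the membrane protein Emp1 (-7.24 ± 1.52) and the beta globin Hbb-bt (-7.23 ± 1.11). They were also higher in the growth factor Igf2 (-7.19 ± 0.92), the matrix protein Ccn1 (-6.95 ± 1.59) and the neurexin Nrxn2 (-6.86 ± 0.66). Each SE pools the spread within all 4 groups and so also takes in the E15.5 arrays, which are in neither fraction. Col3a1 was at 12.46 in E15.5 replicate 2, against 6.08 and 6.38 in E15.5 replicates 1 and 3. Stc1 was at least 142-fold, the alpha globin Hba-a1 at least 106-fold, the collagen Col6a1 at least 83.1-fold and the T-box factor Tbx3 at least 80.01-fold higher in non-germ cells than in germ cells, where none of them was detected.

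Germ cell lists were called higher in the sorted fraction at the preset correlation, and 6 lists of somatic cell markers lower. With an estimated correlation none of these 6 kept its call with all arrays, and interstitial markers did without E15.5 replicate 2 (adjusted p = 0.0259). Of pluripotency genes 18 of 20 measured were higher and 1 lower (the same adjusted over the list alone, set test adjusted p = 1.31e-10, and adjusted p = 0.0438 with an estimated correlation). The exception was Tbx3, a T-box factor also active in mesenchyme. Of early primordial germ cell genes 13 of 16 measured were higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 4.25e-05, and adjusted p = 0.0438 with an estimated correlation). Dnd1 was at least 24.5-fold higher and the integrin subunit Itgb1 differed by -1.39 ± 0.26. Of germ cell identity and genome defence genes 20 of 22 measured were higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 1.31e-10, and adjusted p = 0.238 with an estimated correlation). Male germ cell differentiation genes were 12 higher and 1 lower of 15 measured (the same adjusted over the list alone, set test adjusted p = 0.000132, and adjusted p = 0.238 with an estimated correlation), and 11 of the 15 are also on other lists. Nanos2 was at least 47.2-fold and the piRNA helicase Mov10l1 at least 41.7-fold higher. Meiosis genes were 19 higher and 0 lower of 22 measured (the same adjusted over the list alone, set test adjusted p = 1.16e-07, and adjusted p = 0.0937 with an estimated correlation). The recombination enzyme Spo11 was at least 16.3-fold and the cohesin Smc1b at least 11.9-fold higher. DNA replication genes were 19 higher and 1 lower of 28 measured (the same adjusted over the list alone, set test adjusted p = 0.000536, and adjusted p = 0.315 with an estimated correlation). The replication initiator Mcm10 differed by 2.09 ± 0.24. Mitosis genes were 21 higher and 1 lower of 26 measured (the same adjusted over the list alone, set test adjusted p = 2.88e-06, and adjusted p = 0.286 with an estimated correlation). The checkpoint gene Mad2l1 differed by 2.92 ± 0.24 and the cytokinesis gene Anln by 2.46 ± 0.24. Oxidative phosphorylation genes were 18 higher and 0 lower of 28 measured (the same adjusted over the list alone, set test adjusted p = 0.000422, and adjusted p = 0.0438 with an estimated correlation). The complex IV subunit Cox5a differed by 2.09 ± 0.19. Polycomb and histone methylation genes were 14 higher and 1 lower of 24 measured (the same adjusted over the list alone, set test adjusted p = 0.0153, and adjusted p = 0.308 with an estimated correlation). Suv39h2 differed by 2.07 ± 0.20.

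Imprinted genes were 2 higher and 20 lower of 26 measured (3 and 20 adjusted over the list alone, set test adjusted p = 5.51e-06, and adjusted p = 0.273 with an estimated correlation). Dlk1 differed by -6.51 ± 0.86 and the deubiquitinase Usp29 by 2.89 ± 0.37. Sertoli cell markers were 1 higher and 16 lower of 19 measured (1 and 17 adjusted over the list alone, set test adjusted p = 0.000189, and adjusted p = 0.308 with an estimated correlation). Sox9 differed by -5.09 ± 0.87, and the exception Dmrt1, a factor that germ cells also express, was at least 21.6-fold higher. Interstitial markers were 0 higher and 16 lower of 17 measured (0 and 17 adjusted over the list alone, set test adjusted p = 5.03e-07, and adjusted p = 0.308 with an estimated correlation). Lum was at least 56.6-fold lower. Endothelial markers were 1 higher and 9 lower of 13 measured (1 and 11 adjusted over the list alone, set test adjusted p = 0.00447, and adjusted p = 0.378 with an estimated correlation). Ramp2 was at least 9.88-fold lower. Erythroid markers were 0 higher and 6 lower of 7 measured (the same adjusted over the list alone, set test adjusted p = 0.0033, and adjusted p = 0.308 with an estimated correlation). Leukocyte markers were 0 higher and 6 lower of 10 measured (the same adjusted over the list alone, set test adjusted p = 0.0138, and adjusted p = 0.369 with an estimated correlation). Laptm5 was at least 2.52-fold lower. Mesonephric and epithelial markers were 1 higher and 6 lower of 9 measured (1 and 7 adjusted over the list alone, set test adjusted p = 0.022, and adjusted p = 0.238 with an estimated correlation). Emx2 was at least 14.03-fold lower and Lhx1 differed by 2.59 ± 0.19. Immediate early and heat shock genes were 2 higher and 11 lower of 16 measured (the same adjusted over the list alone, set test adjusted p = 0.00431, and adjusted p = 0.378 with an estimated correlation). Fosb differed by -5.70 ± 1.05 and Fos by -4.63 ± 0.82. Fetal Leydig cell markers were 1 higher and 2 lower of 9 measured (the same adjusted over the list alone) and ovarian somatic markers 0 higher and 2 lower of 4 measured (the same adjusted over the list alone), with Wnt4 at least 4.88-fold lower, but the set test called neither (adjusted p = 0.313 and 0.207). Fetal Leydig markers were 5 lower of 7 measured without E15.5 replicate 2. The endothelial and leukocyte calls ended without non-germ replicate 2 (both adjusted p = 0.218), the leukocyte call also with detection on at least 3 arrays (0.0758) and the mesonephric call with cyclic loess (0.0533).

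Of 11598 genes, limma called 3567 higher and 3043 lower in germ than in non-germ cells, 2158 and 2274 of them at least 2-fold. The values of both groups did not overlap for 74.5% of all genes, where chance gives 20%. Nor did they for any gene named above with a call, but the naming rule required this of the largest changes. Camera called 17 of 29 lists, and with an estimated correlation pluripotency, early primordial germ cell and oxidative phosphorylation genes kept their calls. When E15.5 replicate 2 was left out as well, oxidative phosphorylation genes lost theirs (adjusted p = 0.0846). Meiosis, imprinted and interstitial genes, not called this way with all arrays, were then called (each adjusted p = 0.0259). The median and mean of G1 to S cyclins (0.152 and -0.468) and of glycolysis genes (0.108 and -0.311) differed in sign, and camera, which called neither list, gave both as lower. Cyclic loess turned the balance of calls to 2630 higher and 3869 lower (40.5% higher against 54%) and moved the median of all genes by -0.233. With arrays left out Nrxn2 differed by -3.43 without E11.5 replicate 1 and by -3.48 and -3.41 without either non-germ array. E11.5 replicate 1 is in neither group. Each such fit chose the probe of a gene anew, and whether the Nrxn2 probe changed was not checked.

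The first interval compared male germ cells at E13.5 with the germ cells of E11.5, which are labelled male/female. Nanos2 rose at least 38.4-fold from undetected (adjusted p = 2.9e-07, 3 arrays per group). The Ras exchange factor Rasgrp1 rose at least 12.99-fold (2.43e-06), the secreted protein Ucma at least 12.97-fold (8.88e-06) and the glutathione transferase Mgst2 at least 10.3-fold (2.05e-05). The largest rises among genes seen at both stages were those of Retreg1, a receptor of endoplasmic reticulum turnover (log2 5.18 ± 0.28, adjusted p = 2.27e-06), the POU factor Pou6f1 (4.21 ± 0.22) and Irf2bpl (4.06 ± 0.20). Next came the zinc finger gene Bnc2 (3.82 ± 0.17), the dynein chain Dnaic1 (3.49 ± 0.19) and Cthrc1 (3.33 ± 0.28). The germ cell homeobox genes Rhox6 and Rhox9 fell (log2 -4.38 ± 0.18 and -4.15 ± 0.33, adjusted p = 7.23e-07 and 2.36e-05). The actin-binding Tmsb4x (-4.14 ± 1.17, adjusted p = 0.0332), the guidance ligand Slit2 (-4.01 ± 0.89, adjusted p = 0.0104), H2-Bl (-3.88 ± 0.30) and the iodide transporter Slc5a5 (-3.66 ± 0.21) also fell. The homeobox gene Cdx2 fell at least 15.7-fold to undetected and Serpinb9b at least 14.3-fold. The glutamate transporter Slc1a3 fell at least 12.2-fold and Porcn, which acylates Wnt proteins, at least 9.76-fold.

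Germ cell identity and genome defence genes were called higher as a set between E11.5 and E13.5 at the preset correlation only. Of them 13 of 22 measured were higher and 0 lower (18 and 0 adjusted over the list alone, set test adjusted p = 3.55e-08, and adjusted p = 0.387 with an estimated correlation). The Tudor domain gene Tdrd7 was at least 5.49-fold higher, and Tdrd5 rose by 1.97 ± 0.20 and Ddx4 by 1.13 ± 0.15. Of male germ cell differentiation genes 8 of 15 measured were higher and 0 lower (10 and 0 adjusted over the list alone, set test adjusted p = 1.66e-06, and adjusted p = 0.32 with an estimated correlation). Egr4 was at least 6.69-fold higher. Of genes of meiosis and the retinoic acid response 8 of 22 measured were higher and 0 lower (8 and 1 adjusted over the list alone, set test adjusted p = 0.00214, and adjusted p = 0.387 with an estimated correlation). The synaptonemal complex genes Sycp1 and Sycp2 were at least 4.38 and 1.91-fold higher. Of DNA replication genes 0 of 28 measured were higher and 5 lower (the same adjusted over the list alone, set test adjusted p = 0.000144, and adjusted p = 0.387 with an estimated correlation). The ribonucleotide reductase Rrm1 changed by -1.45 ± 0.25 and the licensing factor Cdc6 by -1.36 ± 0.31. Of pluripotency genes 1 of 20 measured was higher and 5 lower (the same adjusted over the list alone, set test adjusted p = 0.0189, and adjusted p = 0.387 with an estimated correlation). Klf2 changed by -1.81 ± 0.27 and Sox2 by -0.82 ± 0.24 (adjusted p = 0.0374). Nanog at 11.98 and 11.86 (adjusted p = 0.8) and Pou5f1 at 11.05 and 10.67 (adjusted p = 0.18) did not pass. Of early primordial germ cell genes 2 of 16 measured were higher and 6 lower (3 and 6 adjusted over the list alone, set test adjusted p = 0.00782, and adjusted p = 0.315 with an estimated correlation). Of imprinted genes 2 of 26 measured were higher and 5 lower (2 and 6 adjusted over the list alone, set test adjusted p = 0.0448, and adjusted p = 0.744 with an estimated correlation). The placental growth gene Phlda2 changed by -3.27 ± 0.18 and the amino acid transporter Slc38a4 by -2.29 ± 0.18. Of glycolysis genes 1 of 16 measured was higher and 3 lower (1 and 6 adjusted over the list alone, set test adjusted p = 0.0259, and adjusted p = 0.371 with an estimated correlation). The lactate dehydrogenase Ldha changed by -1.24 ± 0.27. Glycolysis lost its call without E11.5 replicate 1 (adjusted p = 0.0582), E11.5 replicate 2 (0.0501) or E13.5 replicate 2 (0.0554). Imprinted genes lost it without E11.5 replicate 1 (0.086), E13.5 replicates 2 (0.0562) or 3 (0.0699), or E15.5 replicates 1 (0.057) or 3 (0.0501). They also lost it with no background correction (0.077), an offset of 50 (0.0644), the authors' table (0.0936), the compared groups normalized alone (0.0503), the mean of all probes (0.0664) and fry (0.0648). DNA replication genes were lower for 9 genes without E15.5 replicate 2, glycolysis genes for 7 and imprinted genes for 8, with 4 imprinted genes higher.

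Several genes changed on lists that the set test did not call. The DNA methyltransferase Dnmt3b rose by log2 1.58 ± 0.13 (adjusted p = 3.37e-05) and the stress gene Gadd45b changed by -1.96 ± 0.28. Of DNA methylation machinery 3 of 13 measured were higher and 4 lower (4 and 5 adjusted over the list alone, set test adjusted p = 0.77). The Nodal antagonist Lefty1 rose by 2.77 ± 0.19 and the Nodal effector Foxh1 changed by -2.05 ± 0.18. Of Nodal and activin genes 2 of 13 measured were higher and 2 lower (3 and 2 adjusted over the list alone, set test adjusted p = 0.946). The cell cycle inhibitors Cdkn2a and Cdkn1b rose by 1.73 ± 0.25 and 1.56 ± 0.24, and Gadd45a changed by -3.11 ± 0.26. Of inhibitors and pocket proteins 4 of 14 measured were higher and 2 lower (5 and 2 adjusted over the list alone, set test adjusted p = 0.541). The claudin Cldn7 changed by -3.37 ± 0.33. Of adhesion and migration genes 2 of 14 measured were higher and 3 lower (2 and 5 adjusted over the list alone, set test adjusted p = 0.0759). Mitosis genes were 1 higher and 1 lower of 26 measured (0 and 1 adjusted over the list alone, set test adjusted p = 0.817) and G1 to S cyclins 1 higher and 2 lower of 12 measured (1 and 3 adjusted over the list alone, set test adjusted p = 0.177). FGF and ERK targets were 1 higher and 2 lower of 13 measured (the same adjusted over the list alone, set test adjusted p = 0.0815), ribosomal proteins 2 higher and 0 lower of 22 measured (1 and 0 adjusted over the list alone, set test adjusted p = 0.817) and oxidative phosphorylation genes 1 higher and 1 lower of 28 measured (0 and 0 adjusted over the list alone, set test adjusted p = 0.733). Of the Y-linked genes 2 of 5 measured were higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.177). Eif2s3y changed by 1.04 ± 0.31 (adjusted p = 0.0389), and Xist fell (log2 -0.92 ± 0.27, adjusted p = 0.0393). Of immediate early and heat shock genes 1 of 16 measured was higher and 4 lower (the same adjusted over the list alone, set test adjusted p = 0.206), and 6 were lower without E15.5 replicate 2. Without that array 4 Nodal genes were higher and 5 adhesion genes lower. Sertoli cell markers were 1 higher and 0 lower of 19 measured (the same adjusted over the list alone, set test adjusted p = 0.878) and interstitial markers 1 higher and 0 lower of 17 measured (the same adjusted over the list alone, set test adjusted p = 0.733).

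Limma called 1257 genes higher and 921 lower at E13.5 than at E11.5, 627 and 462 of them at least 2-fold. Without E15.5 replicate 2, which is in neither stage, the counts were 1560 and 1278, and 99.5% of the calls were shared. The values of both stages did not overlap for 40.8% of all genes, where chance gives 10%. Nor did they for any gene named for this interval with a call, which the naming rule required of the largest changes. Median scaling called 1018 higher and 616 lower (62.3% higher against 57.7%), and the authors' table turned the balance to 1093 and 1130 (49.2%). Camera called 8 of 29 lists, and with an estimated correlation none kept its call, the lowest adjusted p being 0.315. The median and mean differed in sign for mitosis (0.0406 and -0.0233, lower by camera) and leukocyte markers (-0.0747 and 0.0426, lower by camera), neither of them called. Fewer genes were called lower without E11.5 replicate 1 (594), E13.5 replicate 1 (613) or E13.5 replicate 2 (608), and fewer higher without E13.5 replicate 1 (837). Single arrays also decided some calls: Tmsb4x lost its own without any 1 of the 6 arrays compared (adjusted p from 0.0578 to 0.101), as did Sox2 (up to 0.126). Slit2 and Cdc6 lost it without E13.5 replicate 1 (0.0756 and 0.0526). Eif2s3y lost it without any of these arrays but E11.5 replicate 3 (up to 0.13, and with a log2 of 0.66 without E11.5 replicate 2). Xist lost it without any but E11.5 replicate 2 and E13.5 replicate 1 (up to 0.136). Xist, Eif2s3y and Sox2 also lost it without either non-germ array, and Eif2s3y without E15.5 replicate 3 (0.0512). With no background correction Tmsb4x changed by -1.94 (0.0615) and Xist by -0.29 (0.0709). With the authors' table they changed by -1.71 (0.0675) and -0.22 (0.116), so that neither was called. Tmsb4x also lost its call with robust variances (0.0797) and Sox2 with median scaling (0.0747). Xist and Eif2s3y lost theirs with only the compared groups in the fit (0.061 and 0.0553) and with no filter (0.0536 and 0.0541). Eif2s3y also lost it with median scaling (0.0645) and changed by 0.62 with the mean of its probes (0.0514).

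The second interval compared E15.5 with E13.5 male germ cells. Dnmt3l, detected on 1 of 3 arrays at E13.5, rose by log2 5.87 ± 0.39 (adjusted p = 3.06e-06, 3 arrays per group) and the germ cell transcription factor Sohlh1 by 5.59 ± 0.41 (adjusted p = 6.43e-06). Other large rises were those of the membrane protein Tmc7 (5.47 ± 0.48), Nlrp4f (5.37 ± 0.34), Nckap5 (4.65 ± 0.34) and the RNA export factor Nxf2 (4.49 ± 0.49). The metallothionein Mt1 was at least 23.5-fold and the scaffold protein Mpp3 at least 23.3-fold higher at E15.5. The zinc finger factor Prdm16 was at least 15.96-fold and the carnitine transporter Slc22a16 at least 15.54-fold higher at E15.5, all from undetected (adjusted p from 1.08e-07 to 2.24e-06). The adaptor subunit Ap3b2 (-3.89 ± 0.22), the Nodal antagonist Lefty1 (-3.76 ± 0.19, adjusted p = 7.85e-07) and the LIM homeobox gene Lhx1 (-3.65 ± 0.17) fell. So did the ETS factor Etv1 (-3.63 ± 0.31), the RNA-binding L1td1 (-3.44 ± 0.26) and the creatine kinase Ckb (-3.38 ± 0.27). Lefty2, a second Nodal antagonist, fell at least 11.8-fold to undetected, the homeobox gene Otx2 at least 11.2-fold, Sohlh2 at least 6.38-fold and Usp29 at least 4.97-fold.

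At the preset correlation, lists of Nodal signalling, pluripotency and cell division genes were each called lower at E15.5 than at E13.5. Of Nodal and activin genes 0 of 13 measured were higher and 10 lower (the same adjusted over the list alone, set test adjusted p = 0.000205, and adjusted p = 0.044 with an estimated correlation). Without E15.5 replicate 2 the latter was 0.115. Of pluripotency genes 1 of 20 measured was higher and 11 lower (2 and 11 adjusted over the list alone, set test adjusted p = 0.0019, and adjusted p = 0.4 with an estimated correlation). Of these, 3 were higher without E15.5 replicate 2. Esrrb changed by -2.53 ± 0.19, Sox2 by -1.93 ± 0.24 and Nanog by -1.46 ± 0.23, while Pou5f1 did not pass (10.67 and 10.42, adjusted p = 0.282). Of early primordial germ cell genes 1 of 16 measured was higher and 8 lower (the same adjusted over the list alone, set test adjusted p = 0.00858, and adjusted p = 0.129 with an estimated correlation). The transcriptional repressor Prdm1 changed by -2.57 ± 0.26. Of DNA replication genes 0 of 28 measured were higher and 19 lower (the same adjusted over the list alone, set test adjusted p = 4.76e-06, and adjusted p = 0.4 with an estimated correlation). The thymidylate synthase Tyms changed by -2.14 ± 0.31 and the helicase subunit Mcm2 by -2.07 ± 0.23. Of mitosis genes 0 of 26 measured were higher and 19 lower (1 and 19 adjusted over the list alone, set test adjusted p = 4.76e-06, and adjusted p = 0.4 with an estimated correlation). The mitotic kinase genes Aurkb and Plk1 changed by -2.13 ± 0.39 and -2.09 ± 0.22. Of G1 to S cyclins and kinases 0 of 12 measured were higher and 7 lower (1 and 7 adjusted over the list alone, set test adjusted p = 0.0235, and adjusted p = 0.588 with an estimated correlation). The phosphatase Cdc25a changed by -1.53 ± 0.22, and the call of the list ended without E15.5 replicate 1 (adjusted p = 0.066) and with the compared groups normalized alone (0.0545). Of oxidative phosphorylation genes 2 of 28 measured were higher and 18 lower (the same adjusted over the list alone, set test adjusted p = 0.000137, and adjusted p = 0.044 with an estimated correlation, or 0.139 with an estimated correlation and without E15.5 replicate 2). The complex I subunit Ndufa5 changed by -1.44 ± 0.17 and Cox5a by -1.42 ± 0.17.

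More genome defence genes rose than fell in the second interval. Of germ cell identity and genome defence genes 14 of 22 measured were higher and 3 lower (the same adjusted over the list alone, set test adjusted p = 0.0015, and adjusted p = 0.691 with an estimated correlation). The helicase Tdrd9 changed by 4.31 ± 0.38 and the piRNA factor Gtsf1 by 3.75 ± 0.39, whereas Tdrd12 (-0.76 ± 0.18) and Dazl (-0.73 ± 0.18) fell. Male germ cell differentiation genes were 8 higher and 3 lower of 15 measured (the same adjusted over the list alone), not called as a set (adjusted p = 0.232). Of meiosis genes 6 of 22 measured were higher and 3 lower (6 and 2 adjusted over the list alone, set test adjusted p = 0.333). Stra8 was at least 1.36-fold higher (adjusted p = 0.00791, detected on 2 of 3 E15.5 arrays and not tested without replicate 2). The recombination gene Tex15 changed by 1.67 ± 0.23 and the synaptonemal complex gene Syce2 by -2.21 ± 0.22. The methyltransferase Dnmt3a rose by 2.43 ± 0.29 and Tet1, an enzyme of methylcytosine oxidation, changed by -3.12 ± 0.29. Of DNA methylation machinery 5 of 13 measured were higher and 5 lower (5 and 6 adjusted over the list alone, set test adjusted p = 0.97). Imprinted genes were 8 higher and 2 lower of 26 measured (the same adjusted over the list alone), not called (adjusted p = 0.114). They were 8 higher and 7 lower without E15.5 replicate 2. Peg10 changed by 3.96 ± 0.52 and Dlk1 by 4.15 ± 0.77, or 3.22 without E15.5 replicate 2. Of FGF and ERK targets 2 of 13 measured were higher and 6 lower (the same adjusted over the list alone, set test adjusted p = 0.0913, and 0.0344 without E15.5 replicate 2, where it was adjusted p = 0.217 with an estimated correlation). The phosphatase Dusp4 changed by -3.08 ± 0.31. Cell cycle inhibitors and pocket proteins were 4 higher and 2 lower of 14 measured (the same adjusted over the list alone, set test adjusted p = 0.587) and glycolysis genes 4 higher and 6 lower of 16 measured (4 and 7 adjusted over the list alone, set test adjusted p = 0.291). Ribosomal proteins were 0 higher and 2 lower of 22 measured (0 and 1 adjusted over the list alone, set test adjusted p = 0.247) and adhesion genes 0 higher and 2 lower of 14 measured (0 and 1 adjusted over the list alone, set test adjusted p = 0.563).

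Of the lists of other gonadal cells, the set test called Sertoli and interstitial markers in this interval, and neither without E15.5 replicate 2. Of Sertoli cell markers 4 of 19 measured were higher and 1 lower (the same adjusted over the list alone, set test adjusted p = 0.0295, and adjusted p = 0.691 with an estimated correlation). Sox9 changed by 4.15 ± 0.78, or 3.58 without E15.5 replicate 2 (adjusted p = 0.00173 and 0.00377). Of interstitial markers 5 of 17 measured were higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.0126, and adjusted p = 0.691 with an estimated correlation). The receptor Pdgfra changed by 3.84 ± 0.55, or 3.12 without that array. Without it the set test called neither list (adjusted p = 0.252 and 0.0731), although 4 and 4 members were still called higher, and the Sertoli list also lost its call without E13.5 replicate 1 (adjusted p = 0.0661). The Sertoli call ended as well with cyclic loess (0.0627), the compared groups normalized alone (0.112), array weights (0.103) and fry (0.0507), and the interstitial call with array weights (0.0745) and fry (0.0855). Of immediate early and heat shock genes, which respond to stress and handling, 9 of 16 measured were higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.00858, and adjusted p = 0.691 with an estimated correlation), and 8 were higher without E15.5 replicate 2. Endothelial markers were 3 higher and 2 lower of 13 measured (the same adjusted over the list alone, set test adjusted p = 0.234) and erythroid markers 1 higher and 0 lower of 7 measured (the same adjusted over the list alone, set test adjusted p = 0.381). Leukocyte markers were 2 higher and 0 lower of 10 measured (the same adjusted over the list alone, set test adjusted p = 0.247) and fetal Leydig cell markers 0 higher and 0 lower of 9 measured (the same adjusted over the list alone, set test adjusted p = 0.776). Mesonephric and epithelial markers were 0 higher and 1 lower of 9 measured (the same adjusted over the list alone, set test adjusted p = 0.97), ovarian somatic markers 0 higher and 0 lower of 4 measured (the same adjusted over the list alone, set test adjusted p = 0.97) and Y-linked genes 1 higher and 0 lower of 5 measured (the same adjusted over the list alone, set test adjusted p = 0.97). Nanos2 (11.38 and 11.30), Ddx4, Eif2s3y, Xist and Amh did not pass (adjusted p = 0.803, 0.273, 0.562, 0.522 and 0.186).

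Limma called 2453 genes higher and 2481 lower at E15.5 than at E13.5, 1431 and 1141 of them at least 2-fold. Without E15.5 replicate 2 the counts were 2515 and 2543, and 89.3% of the calls were shared. The values of the stages did not overlap for 51.1% of all genes, where chance gives 10%. Nor did they for any gene named for this interval with a call, as the naming rule required of the largest changes. Camera called 11 of 29 lists, of which Nodal and activin and oxidative phosphorylation genes kept their calls with an estimated correlation. Without E15.5 replicate 2 it called 10, and none kept its call with an estimated correlation (lowest adjusted p = 0.115). The median and mean differed in sign for DNA methylation machinery (-0.109 and 0.29), mesonephric markers (0.241 and -0.0756) and Y-linked genes (-0.24 and 0.124). Camera gave these, and ovarian markers with a median of 0.0298, as lower without calling them. Median scaling called 1821 higher and 2788 lower (39.5% higher against 49.7%) and moved the median of all genes by -0.139. Cyclic loess called 2973 and 1915 (60.8% higher) and moved it by 0.12.

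**Figure D3:**
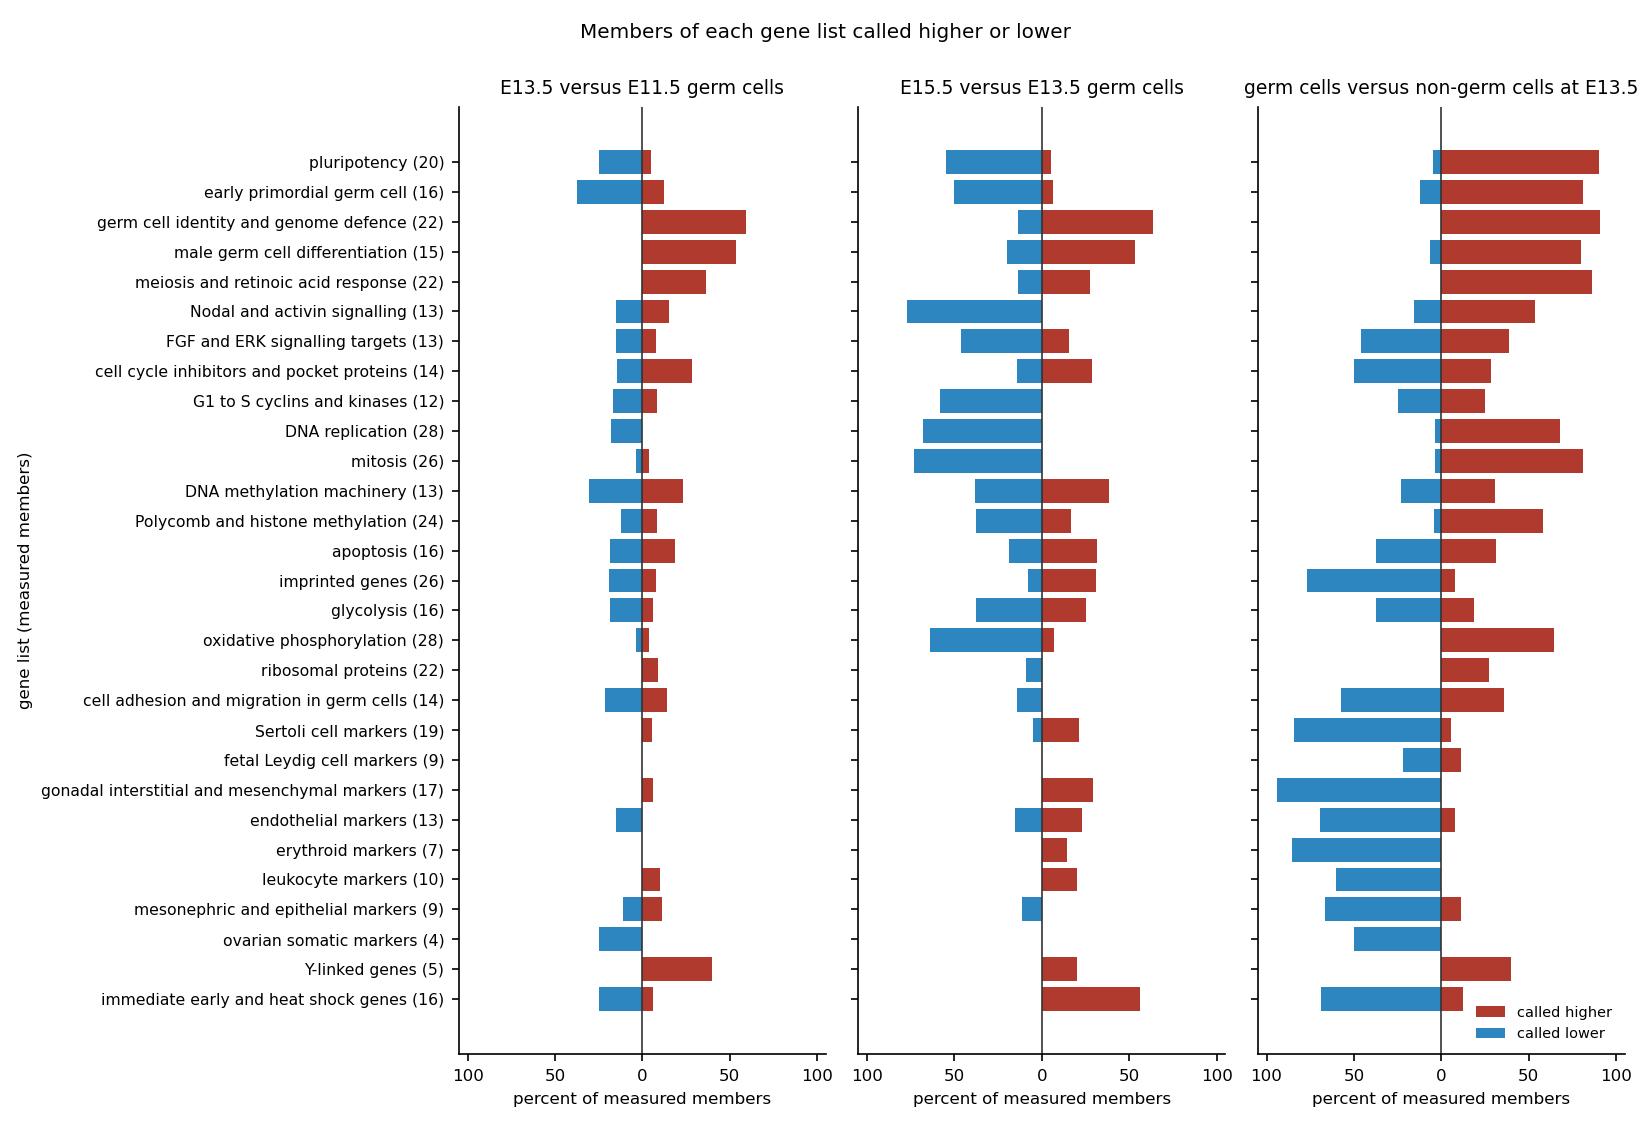
Percent of the measured genes of each list called higher (right) and lower (left) in 3 comparisons. These are E13.5 against E11.5 germ cells, E15.5 against E13.5 germ cells, and germ against non-germ cells at E13.5. Of DNA replication genes 19 of 28 were lower at E15.5 than at E13.5, and of genome defence genes 14 of 22 were higher.

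The whole course, from E11.5 to E15.5, was compared directly. Dnmt3l rose at least 56.99-fold (adjusted p = 4.65e-07, 3 arrays per group), Nxf2 at least 38.1-fold, Nanos2 at least 36.4-fold and Tspoap1 at least 34.99-fold. Sohlh1 rose by log2 6.35 ± 0.41, Tdrd9 by 5.53 ± 0.38 and Nckap5 by 5.07 ± 0.34. The ion channel gene Pkd2l1 rose by 5.03 ± 0.45, the PIWI gene Piwil1 by 4.91 ± 0.22 and Pou6f1 by 4.77 ± 0.22. Rhox9 fell at least 54.1-fold, Rhox6 at least 33.5-fold, Cdx2 at least 17.8-fold and the mitochondrial creatine kinase Ckmt2 at least 13.4-fold. Ckb (-4.99 ± 0.27), the nucleosome-binding Hmgn5 (-4.53 ± 0.23), Vrtn (-4.42 ± 0.27), Serpinb9b (-4.39 ± 0.26), the homeobox gene Gbx2 (-4.31 ± 0.22) and the desmosomal cadherin Dsg2 (-4.29 ± 0.50) fell. Sox2 changed by -2.76 ± 0.24, Nanog by -1.57 ± 0.23, Pou5f1 by -0.63 ± 0.18 (adjusted p = 0.0133) and Xist by -1.15 ± 0.27. Ddx4 rose by 1.34 ± 0.15, although another of its probes changed by -0.69, and Sox9 rose by 4.57 ± 0.78. Stra8 was at least 1.41-fold higher, Amh was undetected at both stages, and Dazl and Eif2s3y did not pass (adjusted p = 0.93 and 0.0506). Eif2s3y passed without E11.5 replicate 3 (0.0157) or E15.5 replicate 2 (0.0419).

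Of DNA replication genes 0 of 28 measured were higher and 23 lower (0 and 24 adjusted over the list alone) between E11.5 and E15.5 (adjusted p = 9.61e-09, and adjusted p = 0.218 with an estimated correlation). Tyms changed by -3.11 ± 0.31 and the thymidine kinase Tk1 by -2.80 ± 0.49. Mitosis genes were 0 higher and 18 lower of 26 measured (0 and 19 adjusted over the list alone, set test adjusted p = 5.77e-06, and adjusted p = 0.249 with an estimated correlation). G1 to S cyclins were 2 higher and 9 lower of 12 measured (the same adjusted over the list alone, set test adjusted p = 0.00753, and adjusted p = 0.276 with an estimated correlation). Genome defence genes were 17 higher and 1 lower of 22 measured (the same adjusted over the list alone, set test adjusted p = 2.93e-07, and adjusted p = 0.249 with an estimated correlation). Gtsf1 was at least 16.7-fold higher. Male germ cell differentiation genes were 12 higher and 3 lower of 15 measured (the same adjusted over the list alone, set test adjusted p = 0.00144, and adjusted p = 0.249 with an estimated correlation). Meiosis genes were 13 higher and 1 lower of 22 measured (14 and 1 adjusted over the list alone, set test adjusted p = 0.00753, and adjusted p = 0.276 with an estimated correlation). Sycp2 was at least 4.82-fold higher, and Tex12 changed by 3.05 ± 0.20 and Syce2 by -2.85 ± 0.22. Pluripotency genes were 2 higher and 12 lower of 20 measured (2 and 13 adjusted over the list alone, set test adjusted p = 0.000152, and adjusted p = 0.218 with an estimated correlation). L1td1 changed by -3.65 ± 0.26 and Klf2 by -3.38 ± 0.27, but Klf4 was at least 4.32-fold higher. Early primordial germ cell genes were 1 higher and 10 lower of 16 measured (the same adjusted over the list alone, set test adjusted p = 0.000644, and adjusted p = 0.0665 with an estimated correlation). Nodal and activin genes were 0 higher and 9 lower of 13 measured (the same adjusted over the list alone, set test adjusted p = 0.00154, and adjusted p = 0.071 with an estimated correlation). FGF and ERK targets were 2 higher and 9 lower of 13 measured (the same adjusted over the list alone, set test adjusted p = 0.0136, and adjusted p = 0.249 with an estimated correlation). Dusp4 changed by -3.51 ± 0.31 and Etv5 by -2.38 ± 0.20. Oxidative phosphorylation genes were 1 higher and 17 lower of 28 measured (2 and 17 adjusted over the list alone, set test adjusted p = 0.000316, and adjusted p = 0.0665 with an estimated correlation). Glycolysis genes were 1 higher and 8 lower of 16 measured (the same adjusted over the list alone, set test adjusted p = 0.0297, and adjusted p = 0.249 with an estimated correlation). The kinase Pgk1 changed by -1.67 ± 0.20. Adhesion genes were 1 higher and 8 lower of 14 measured (the same adjusted over the list alone, set test adjusted p = 0.0478, and adjusted p = 0.249 with an estimated correlation), and Cldn7 changed by -3.53 ± 0.33. Sertoli cell markers were 6 higher and 0 lower of 19 measured (the same adjusted over the list alone, set test adjusted p = 0.0304, and adjusted p = 0.682 with an estimated correlation). Interstitial markers were 6 higher and 0 lower of 17 measured (3 and 0 adjusted over the list alone, set test adjusted p = 0.0395, and adjusted p = 0.717 with an estimated correlation). Neither was called without E15.5 replicate 2 (adjusted p = 0.251 and 0.447). The interstitial call also ended without E11.5 replicates 2 (0.0732) or 3 (0.0504). The adhesion call ended without any germ cell array but E13.5 replicate 2 and E15.5 replicate 2 (adjusted p from 0.0504 to 0.0861). It also ended with median scaling (0.0501), detection on at least 3 arrays (0.0615), a block by replicate number (0.0587) and without genes of other lists (0.101). The Sertoli call ended with the compared groups normalized alone (0.0622) and array weights (0.0774). The interstitial call ended with these (0.108 and 0.256), with cyclic loess (0.0539) and with fry (0.0973). Oxidative phosphorylation genes were 3 higher without E15.5 replicate 2.

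Limma called 2980 genes higher and 2803 lower at E15.5 than at E11.5, or 3003 and 2881 without E15.5 replicate 2, with 91.4% of calls shared. Values of the 2 stages did not overlap for 55.4% of all genes, where chance gives 10%. Nor did they for any gene named for this course with a call, as the naming rule required of the largest changes. Camera called 15 of 29 lists, none of which kept its call with an estimated correlation, the lowest adjusted p being 0.0665. The median and mean differed in sign for DNA methylation machinery (-0.118 and 0.245), fetal Leydig markers (-0.147 and 0.316), ovarian markers (0.233 and -0.161) and Y-linked genes (-0.114 and 0.748). Camera gave Y-linked genes as higher and the others as lower, calling none. Any change over the 3 stages was called for 6414 genes (55.3%), or 6651 without E15.5 replicate 2. Median scaling turned the balance to 2410 higher and 2912 lower (45.3% higher against 51.5%) and moved the median of all genes by -0.106. Cyclic loess called 3380 and 2321 (59.3%) and moved it by 0.105.

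The contrast of the intervals asked directly whether a gene's change differed between them. Taken with its sign, the log2 change was larger in the second interval for 1348 genes and smaller for 1489. Of these, 1253 and 1307 differed at least 2-fold. A gene that turned from a rise to a fall thus counts as smaller, whatever the size of the fall. The genes named here were chosen after their values were seen. Tdrd9 rose more in the second interval (difference of the log2 changes 3.09 ± 0.65, adjusted p = 0.00725). Lefty1 turned from a rise to a fall (-6.53 ± 0.33, adjusted p = 4.1e-06), and the log2 changes of Mcm2 and Plk1 were lower in the second interval than in the first (-1.91 ± 0.39 and -2.24 ± 0.38, adjusted p = 0.00642 and 0.00236). Without E15.5 replicate 2 the counts were 1607 and 1796. They were lower without E13.5 replicate 1 (957 smaller), replicate 2 (793 and 814) or replicate 3 (838 and 803). Cyclic loess called 1621 larger and 1140 smaller (58.7% larger against 47.5%) and moved the median of all genes by 0.15. Median scaling called 957 and 1519 (38.7%) and moved it by -0.166.

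Genes enriched in either fraction at E13.5 were followed in germ cells from E11.5 to E15.5. Non-germ enriched genes are low in germ cells by this choice, which limits calls of lower. Of 541 germ cell enriched genes 172 (31.8%) were higher and 202 (37.3%) lower at E15.5, against 25.7% and 24.2% of all genes. Of 1113 non-germ enriched genes 400 (35.9%) were higher and 53 (4.76%) lower. Without E15.5 replicate 2, the array with most non-germ transcripts, 205 of 547 germ cell enriched genes (37.5%) were higher and 188 (34.4%) lower. Of non-germ enriched genes, 366 of 1106 (33.1%) were higher and 148 (13.4%) lower. The count of non-germ enriched genes called lower was 35 without E15.5 replicate 1 and 33 without replicate 3.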

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

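The tests on non-germ transcripts in E15.5 replicate 2, and on the share of the same cells in E15.5 replicates 1 and 3, were chosen only after the result was seen, whereas the test of scaling was written before.

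Genes whose level at E13.5 lay apart from both other stages stood out as a difference between groups. At E13.5, 110 genes were called at least 2-fold higher than at E11.5 and at E15.5 (120 without E15.5 replicate 2, 100 of them in both fits) and 118 at least 2-fold lower (112 without it, 97 in both). In 20 simulations without such genes there were 0. Immediate early and heat shock genes, which respond to handling, were 1 higher and 4 lower of 16 from E11.5 to E13.5 (set test adjusted p = 0.206). From E13.5 to E15.5 they were 9 higher and 0 lower (set test adjusted p = 0.00858). Whether handling shaped the pattern was not tested. The second interval minus the first was -7.574 ± 0.46 on the log2 scale for Rasgrp1 (adjusted p = 6.75e-06), -7.434 ± 0.347 for the homeobox gene Hesx1 (3.9e-06), -7.211 ± 0.452 for Otx2 (6.84e-06) and -6.53 ± 0.328 for Lefty1 (4.1e-06). It was 8.008 ± 0.468 for Mt1 (6.4e-06), 7.464 ± 0.467 for the homeobox gene Dlx3 (6.84e-06), 6.785 ± 0.46 for the Rac-binding Cyria (1.16e-05) and 6.577 ± 0.44 for the filamin-binding Fblim1 (1.08e-05). Each of these comes from 3 arrays per stage. Rasgrp1 and Hesx1 were undetected at E11.5, Mt1, Cyria and Fblim1 at E13.5 and Otx2 at E15.5, so the size of their differences rests on values at background. When the 9 germ cell arrays were put into stages at random, 3 of 100 drawn splits, the real one included, called as many genes for a difference between the intervals. The real count was 2837 and the highest other 4794. Such splits ask whether the stages differ at all and not whether the 2 intervals differ, so they cannot decide on the latter. The 2 splits with more calls put all E15.5 arrays or all E11.5 arrays in the middle place. Any change over the 3 stages was called for 6414 genes and for at most 3660 in the other splits. The real split was the only 1 of 100 drawn to call as many, so chance is unlikely to account for this count. The splits do not tell what set the stages apart.

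E15.5 replicate 2 carried transcripts of other gonadal cells, and 87% of 1113 non-germ enriched genes lay above both other E15.5 arrays, where chance gives 33.3%. The excess might come from gonadal cells left in the sorted fraction, and its test did not exclude this, with 80.6% of 541 germ cell enriched genes below both other arrays. RNA of the E13.5 non-germ samples mixed in would bring the embryonic globins Hba-x and Hbb-y, but the larger of their shares was 0.19% against a median of 39.2% for 170 abundant non-germ genes, which argues against it. These shares rest on the mean of the 2 non-germ arrays, whose erythroid marker means differed (11.2 and 8.66). A non-germ sample under a germ cell label is also unlikely, since the germ cell enriched genes fell by only 17.9% of their gap between germ and non-germ cells. No biological explanation was tested, nor how such cells came into the sort.

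Without E15.5 replicate 2, 421 of 1106 non-germ enriched genes were higher and 61 lower at E15.5 than at E13.5, against 2515 and 2543 of all 11360 genes. They were chosen as low on the same E13.5 germ cell arrays, which favours a rise from there, and from E11.5 to E15.5 366 were higher and 148 lower. The same non-germ cells at a lower share in replicates 1 and 3 might account for the rise, and this stays open. The excess in replicate 2 was 1.91 times that in replicates 1 and 3 in the median gene (quartiles 1.14 and 3.91). The lowest ratio predicted, 3.18, lies above the median but below the third quartile, so the test did not decide. For 40 genes above the non-germ level in replicates 1 and 3 the median ratio was 0.887. Genes picked for their excess in these arrays have a low ratio by that choice. Scaling between arrays is unlikely as the whole cause, since 87.6% of the genes kept their call with median scaling and 100% with cyclic loess, and no biological explanation was tested.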

How the results depend on the processing

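Of 4890 values for 196 changes of named genes under the alternatives, 4839 kept direction and side of the threshold, 42 lost the call, 9 gained it and 0 turned. Settings under which a gene was no longer tested are not counted. The naming rule favoured the largest changes on these same arrays, so this share does not describe calls in general. Of 3235 values for 116 list results, 3101 were kept, 96 lost the call, 38 gained it and 0 turned. Many kept values belong to lists that were not called in the main fit. An estimated correlation between genes ended 46 list calls, and fry ended 4 and added 17. With the estimated correlation 0 of 8 calls remained in the first interval and 2 of 11 in the second. From E11.5 to E15.5 it left 0 of 15, and for germ against non-germ cells 3 of 17. A block by replicate number, for which the labels give no ground, ended 0 calls of named genes and 1 list call, adhesion genes from E11.5 to E15.5 (adjusted p = 0.0587). Values of different groups with the same replicate number had correlated deviations (r across genes) of -0.108 to 0.131. A block by slide or chip was not run, since neither is named. Signal over background limits what the arrays can show, and 3 arrays per stage limit the precision.

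Leaving out 1 array at a time gave 837 to 1560 genes higher and 594 to 1278 lower at E13.5 than at E11.5, 1968 to 2515 and 1940 to 2543 at E15.5 against E13.5, and 2631 to 3003 and 2436 to 2881 at E15.5 against E11.5. It gave 2758 to 3756 and 2152 to 3218 for germ against non-germ cells, 793 to 1607 and 803 to 1796 for the difference between the intervals, and 5696 to 6651 for any change. Of germ cell enriched genes 156 to 205 were higher and 186 to 225 lower over time, and of non-germ enriched genes 339 to 509 and 33 to 148. Over all genes each highest count came without E15.5 replicate 2. The fit pools the spread over all groups, so this array enters the spread of every contrast, also of those that do not compare E15.5. How far this accounts for the counts was not tested. Without a non-germ array the lone remaining one is assumed to vary like the other groups.

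Every probe on its own counts more units, with 1480 lower at E13.5 than at E11.5, 3842 and 4572 higher and lower at E15.5 against E13.5, 4747 and 5398 at E15.5 against E11.5, 6441 and 5196 for germ against non-germ cells, 2451 smaller for the interval difference and 11116 for any change. Over time it gave 343 germ cell enriched genes lower, and 608 higher and 83 lower of the non-germ enriched. An adjusted p below 0.01, stricter by construction, called 648 and 430 at E13.5 against E11.5, 1628 and 1595 at E15.5 against E13.5, 658 and 623 for the interval difference, and 29 non-germ enriched genes lower. At least 2-fold called 627 and 462, 1431 and 1141, and 1904 and 1516 in the 3 stage comparisons, 2158 higher in germ cells and 4114 for any change.

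Enriched genes over time depend on how many genes reach 4-fold. Without background correction 35 and 43 germ cell enriched genes were called higher and lower, and 121 and 10 of the non-germ enriched. With the authors' table these were 26, 32, 84 and 4. An offset of 50 gave 132 germ cell and 35 non-germ enriched genes lower. These 3 settings compress differences at low intensity by construction, and without background correction the percents were 35.0%, 43.0%, 35.9% and 2.97%, against 31.8%, 37.3%, 35.9% and 4.76%. Cyclic loess turned the balance of germ cell enriched genes to 38.1% higher and 31.8% lower (126 genes). Array weights gave 101 non-germ enriched genes lower (9.11%). The cause of neither was tested.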

Other observations

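The tests on Y-linked and X-linked genes were chosen only after the result was seen.

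Chromatin and cell death genes changed in both directions in germ cells from E11.5 to E15.5. The H3K27 demethylase Kdm6b rose by log2 2.17 ± 0.15 (3 arrays per group, adjusted p = 1.97e-06) and the H3K9 methyltransferase Ehmt2 by 2.03 ± 0.18, whereas the Polycomb genes Phf19 (-2.95 ± 0.31) and Ezh2 (-1.55 ± 0.17) fell. Polycomb and histone methylation genes were 6 higher and 11 lower of 24 measured (the same adjusted over the list alone), with 7 not passing, and the set test did not call them (adjusted p = 0.257). The de novo methyltransferase Dnmt3b rose by 2.52 ± 0.13, while Tet1 (-2.37 ± 0.29) and Gadd45b (-2.07 ± 0.28) fell, with 4 higher and 6 lower of 13 measured (5 and 6 adjusted over the list alone) of the DNA methylation machinery (adjusted p = 0.707). The survival gene Bcl2l1 was at least 1.91-fold and the BH3 gene Pmaip1 at least 1.97-fold higher, while the BH3 genes Bad (-1.96 ± 0.28) and Bid (-1.25 ± 0.17) fell, with apoptosis genes 6 higher and 2 lower of 16 measured (the same adjusted over the list alone, set test adjusted p = 0.372). The cell cycle inhibitor Cdkn2a rose by 2.65 ± 0.25 and Gadd45a (-2.79 ± 0.26) fell, with 7 higher and 3 lower of 14 measured (the same adjusted over the list alone) of cell cycle inhibitors and pocket proteins (adjusted p = 0.48).

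The 5 measured Y-linked genes had a median log2 change of 0.544 from E11.5 to E13.5, against 0.0135 for 11117 autosomal genes. Of the 5, 2 were called higher, and the set test did not call the list (adjusted p = 0.177). From E11.5 to E15.5, where the later samples are male too, the median was -0.114 and the mean 0.748. There 1 was called higher (set test adjusted p = 0.483). Xist was lower by 0.92, but its call ended with no background correction (-0.29, adjusted p = 0.0709) and with the authors' table (-0.22, adjusted p = 0.116). Female cells in the E11.5 samples, which are labelled male/female, may account for the Y-linked change, and the test did not exclude this, although it also asked for a fall of Xist, which depends on the processing. A second active X chromosome in those cells would lower X-linked genes at E13.5 by about 0.58 if 1 in 2 cells were female. The median of 444 X-linked genes minus that of autosomal genes was -0.0513 (quartiles -0.389 and 0.346), which argues against that share of such cells and leaves a lower one open.

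For comparisons of 6 arrays there are 10 splits into groups of 3, too few for a share under 0.05. In the first interval the real split called 2178 genes and the highest other 0, and 8 lists against 6. In the second interval it called 4934 genes and the highest other 0, and 11 lists against 12, with 3 of the 10 splits calling as many. From E11.5 to E15.5 it called 5783 genes against 0, and 15 lists against 15, with 2 of the splits calling as many. Of germ cell enriched genes it called 374 and the highest other 0, and of non-germ enriched genes 453 against 0.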
